A study of Homo sapiens with 2 samples.

How the data were processed

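The series holds 2 droplet libraries of human pluripotent stem cell derivatives. They are 1 of embryonic-like sacs, labelled posteriorized and pooled from 6 devices, and 1 of transwell amniotic-like cells mixed with H9 cells. The deposited values are counts, raw UMIs per gene and barcode, made with Cell Ranger 3.0.0 against hg19 and analysed by the submitters with Seurat 3.0.0.9, per the submitters' processing notes. Both tables list 32738 genes, and 91 symbols name several of them. Symbols are given as the files print them, with T for brachyury. No gene coordinates are given, because the files name none and the reference at hand is of another build. A merged object of the submitters was not analysed here. The lowest total of any barcode was 500 UMIs in the sac library and 502 in the mixed library.

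Barcodes with under 1500 genes or over 10% mitochondrial UMIs were left out, 590 of the sac and 1228 of the mixed library. Scrublet, through scanpy 1.11.5 with seed 20, then removed 163 and 103 doublets. Kept cells had medians of 22933 UMIs and 4505 genes in the sac library, and 27318 UMIs and 4986 genes in the mixed library.

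Each library was clustered on its own. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen from a random set with 50% of the genes, and no list gene was used. Leiden clustering (leidenalg 0.10.2) ran at resolution 0.5 on 30 principal components and 15 neighbours. Clusters were named from 66 markers of 8 classes, where a marker counted as detected at 20 CPM or more and at least 25% of its highest cluster, and a name needed 3 detected markers of a class. A cluster with as many markers of another class, or whose leading genes belonged to another class, stayed without a name and was called by its number. Neither library holds a tag that tells treated from untreated cells.

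UMIs were summed over the cells of a class and expressed as counts per 1000000 UMIs (CPM). Ratios were taken after adding 5 CPM to both sides, and these decided whether a gene was 2-fold apart or within 2-fold. A gene was compared where the higher class reached 50 CPM and 100 UMIs. Printed folds are ratios of the CPM values themselves with exact 95% binomial intervals, levels have exact Poisson intervals and shares exact Clopper-Pearson intervals. These cover counting error only and are far narrower than the doubt over which cell belongs to which class. Against a class without a UMI the fold was taken against 3 counts and is a lower bound. With 1 library per group no test between groups was possible and none was made.

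Before the data were examined, 23 lists with 288 genes, the markers, the 7 comparisons of classes and the rule for naming genes were set. 4 markers or list genes are not in the tables under their symbols. The lists cover the BMP, WNT, NODAL and FGF pathways, pluripotency and naive pluripotency, germ cells, DNA methylation, paraxial and lateral mesoderm, epithelial and mesenchymal genes, keratins, matrix, amnion, trophoblast, HOX and CDX genes, S and G2/M phases, hypoxia and glycolysis, cholesterol synthesis, immediate-early and heat-shock genes, and p53 targets. The rule names the 10 largest ratios in each direction, without markers, list genes, mitochondrial and ribosomal genes and clone names, and up to 4 members of each list. Genes used for clustering were left out of it within a library and, more strictly than the rule asked, between sac classes and H9. Other list members, markers and leading genes of clusters were named after their values were seen, and so were the comparisons of single clusters. A list's median was placed among 10000 random lists of as many compared genes, matched on mean expression in 20 bins.

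The steps were tested on simulated counts drawn from the real class means and depths, over 32738 genes. The draws were independent Poisson counts, as the intervals assume, without variation between cells or libraries. They therefore check the computation, and not how far real genes or lists vary. In the comparison of transwell amniotic with H9 cells 50 of 50 genes raised 3-fold and 0 of 50 raised 1.5-fold passed 2-fold, and the interval held the true value for 94.7% of unchanged genes. The interval did so for 96.1% between sac and transwell amniotic cells and 95.7% between germ-cell-like and H9 cells. In the same 3 comparisons 1 of 7, 0 of 10 and 0 of 8 unchanged gene lists had a median outside the central 95% of random lists.

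Alternatives covered the gene minimum, the mitochondrial limit, doublets, clustering resolution, the genes used for clustering, clustering both libraries together, the pseudocount, the minimum level, the scaling, the weight of cells and thinning every cell to 10000 UMIs. Naming every cluster by its closest class, and leaving out low-UMI clusters, were added after the data were seen. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.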

Results

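Cells from human embryonic stem cells (hESC) were profiled by droplet RNA sequencing in 2 libraries, with 1 library per condition. The sac library held cells pooled from 6 microfluidic devices in which hESC had built embryonic-like sacs, labelled posteriorized. There the cells had met BMP4, an inducer of amnion and mesoderm, for 48 h. The mixed library held H9 hESC that had met BMP4 for 48 h on transwell membranes, where they become amniotic-like, mixed 2 to 1 with untreated H9 hESC. The sac library had 6735 barcodes and 152740421 molecule counts (UMIs), with a median of 22366 per barcode. The mixed library had 6926 barcodes, 168841189 UMIs and a median of 25087. After filtering, 5982 sac cells and 5595 mixed cells remained. With 1 library per condition no difference had a replicate check, and every interval is a 95% interval that covers counting error only.

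The first question was which cell types the sacs held. Germ-cell-like cells, named from SOX17, NANOS3, PRDM1 and TFAP2C, the regulators that set up the human germ line, made up 19.2% (18.2 to 20.3) of the sac library, or 1151 cells. Amniotic-like cells, named from the ectodermal regulators TFAP2A, GATA3 and DLX5 and the surface protein VTCN1, made up 21.4% (20.4 to 22.5), or 1283 cells. TFAP2A and GATA3 were also at 263 and 168.5 CPM in germ-cell-like cells. GABRP and KRT7 parted the classes better, at 431 and 146 CPM in amniotic-like cluster 1 against 4.37 and 8.58 CPM in germ-cell-like cells. Mesoderm-like cells, named from the mesoderm regulators MESP1 and SNAI2 and the receptor APLNR, made up 43.0% (41.8 to 44.3), or 2575 cells. SOX2, the core pluripotency regulator, stood at 0.0789 CPM (counts per 1000000 UMIs) in mesoderm-like, 0.197 in germ-cell-like and 0.256 in amniotic-like cells, against 222 CPM in the H9 cells of the mixed library, and no sac cluster took the name pluripotent-like. POU5F1, the other core regulator, was still at 2171 CPM in germ-cell-like, 928 CPM in amniotic-like and 692 CPM in mesoderm-like cells, against 1881 in H9. Clusters left without a name held 16.3% (15.3 to 17.2) of sac cells. The largest of them, cluster 2 with 882 cells, carried MESP1, SNAI2 and APLNR but was led by PITX1, HGF and the mesenchyme gene COL1A1. At a clustering resolution of 1.0 a further cluster of 141 sac cells was named pluripotent-like from SFRP2, ZSCAN10, VRTN and POU5F1. CDX4, NTS and GAL were among its leading genes. With doublets kept a cluster of 140 sac cells took the same name from the same markers. SOX2 was not among these markers, and no sac cluster of the main setting held more than 0.307 CPM of it.

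**Figure D1:**
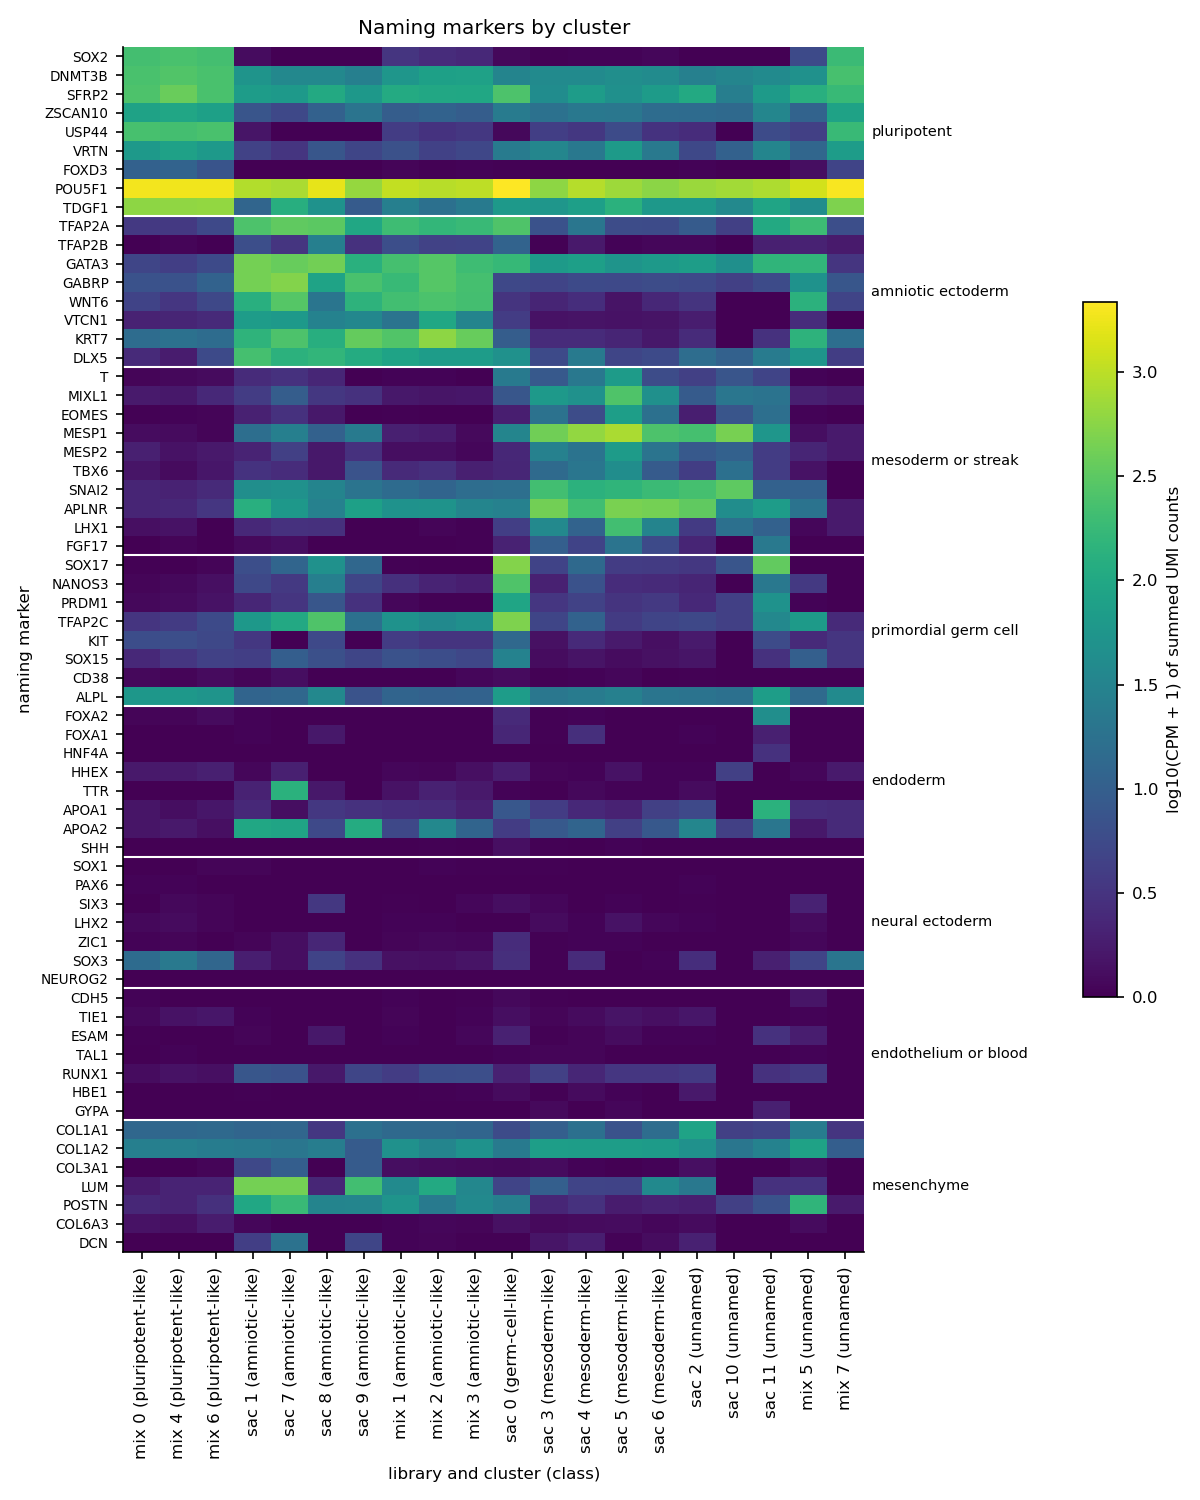
Level of naming markers (log10 of CPM + 1, colour) in each cluster of the sac and mixed libraries. SOX17 reaches 523 CPM in sac cluster 0, the germ-cell-like cells, and SOX2 reaches 222 CPM in the pluripotent-like cells of the mixed library.

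The mixed library served to ask which of its cells were amniotic and which were H9. Pluripotent-like cells, named from SOX2, DNMT3B, USP44 and TDGF1, made up 36.2% (34.9 to 37.5), or 2024 cells, and are the H9 cells of the comparisons. Amniotic-like cells, named from TFAP2A, GATA3, GABRP, WNT6 and KRT7, made up 54.4% (53.04 to 55.7), or 3041 cells, and are the transwell amniotic cells. The leading genes of cluster 3, one of their clusters with 825 cells, were cell-cycle genes such as CENPA, UBE2C, CDK1 and PLK1. Amniotic-like cells were 60.0% (58.7 to 61.4) of the cells with a name, where the mixing ratio gives 66.7%. The share rested on where clusters were drawn. It came to 19.8% of the library at a clustering resolution of 0.3 and 34.9% with doublets kept, because a large cluster with SPP1, NPPB and POSTN then went without a name.

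**Figure D2:**
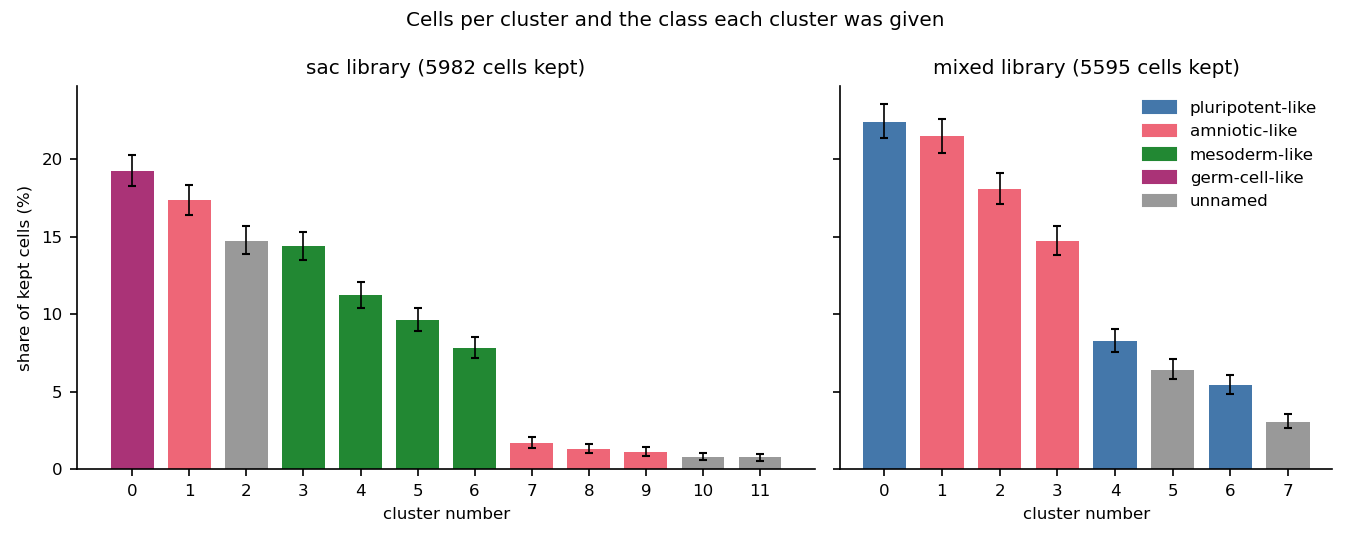
Share of kept cells in each cluster (percent, bars, with exact 95% binomial intervals), by library, coloured by the class the cluster was named. Mesoderm-like cells hold 43.0% of the sac library and amniotic-like cells 54.4% of the mixed library.

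Transwell amniotic cells were set against H9 cells of the same library to see what 48 h of BMP4 on a membrane went with. BMP-response, amnion, keratin and epithelial transcripts were high in them, and most pluripotency transcripts low. WLS, which escorts WNT proteins to the cell surface, was 45.1-fold (41.8 to 48.7) higher at 502 against 11.1 CPM. PPARG, a nuclear receptor of lipid metabolism and placental tissue, was 75.3-fold (61.6 to 92.9) higher, and ABCG2, an efflux pump found in amnion and placenta, 44.4-fold (38.7 to 51.3) higher. IGFBP7, a secreted binder of insulin-like growth factors, was 35.1-fold (31.8 to 39.0) higher, and HAPLN1, which links hyaluronan to proteoglycans, 54.8-fold (49.3 to 61.1) higher. ACTC1, an actin of embryonic muscle, reached 3467 against 109 CPM, and RHOB, a GTPase of endosomes and stress fibres, 272 against 8.41 CPM. TMEM54, RHOBTB3 and the signalling adaptor DOK4 completed the 10 largest ratios, at 28.0-fold, 24.2-fold and 21.5-fold higher. In the other direction LINC00678, a noncoding RNA of stem cells, was 99.3-fold (87.0 to 114) lower, the MYC partner CDCA7L 71.0-fold (59.4 to 85.4) lower, and ZIC2, an enhancer-binding regulator of primed pluripotency, 88.6-fold (70.2 to 114) lower. THY1, the stem-cell surface protein CD90, was at 24.5 against 303 CPM and CENPV, a centromere protein, at 39.2 against 429 CPM.

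Among genes listed before the data were examined, 103 could be compared, of which 45 were at least 2-fold higher in transwell amniotic cells and 14 at least 2-fold higher in H9, with 5 CPM added to both sides here and wherever genes are counted or called within 2-fold. Of 9 BMP-response genes 8 were higher, led by MSX2 at 778 against 26.0 CPM, BAMBI at 1060.2 against 39.6 CPM and GATA2 at 137 against 2.68 CPM; their median log2 ratio was 3.74, percentile 100 among random lists of like expression, as a description of these libraries. ID3 was the member within 2-fold, at 569 against 386 CPM. All 8 measured amnion genes that had no part in naming were higher (median 4.22), among them HAND1 at 1613 against 24.2 CPM, IGFBP3 at 1912 against 40.1 CPM and the hypoxia factor EPAS1 at 440 against 14.1 CPM. The 3 simple-epithelium keratins KRT8, KRT18 and KRT19 were 19.2-fold, 10.0-fold and 22.9-fold higher, and 5 of 7 epithelial adhesion genes were higher, with the tight-junction gene CLDN4 at 269.8 against 11.4 CPM and the adhesion molecule EPCAM at 1915 against 376 CPM. Of 8 pluripotency genes 7 were lower (median -2.57, percentile 0), with NANOG at 1.06 against 54.8 CPM, TERF1 at 143 against 1316 CPM and DPPA4 at 45.3 against 304 CPM, while ZFP42 was within 2-fold at 222 against 148 CPM. Cholesterol-synthesis genes were higher in 6 of 9 cases, led by MVD at 162 against 49.1 CPM, and 5 of 7 immediate-early and stress genes were higher, including EGR1 at 63.2 against 6.38 CPM, JUN at 60.7 against 7.30 CPM and DDIT3 at 74.8 against 7.94 CPM.

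Signalling and patterning genes went both ways. The noncanonical ligand WNT5B was 38.3-fold higher and the WNT antagonist SFRP1 3.16-fold lower, the activin antagonist FST 7.56-fold higher and the NODAL effector FOXH1 8.22-fold lower. ETV4, an output of FGF signalling, was at 8.79 against 92.8 CPM. The HOX genes HOXB2 and HOXB6 were at 175 against 3.19 CPM and 227 against 3.63 CPM, and ISL1, a regulator of amnion and lateral mesoderm, at 110.2 against 2.03 CPM. FN1 and MMP2 were higher and VIM lower among 3 mesenchymal genes, and SPARC and LAMC1 were higher among the matrix genes. Of 12 S-phase genes 2, MCM6 and UNG, were lower and the other 10 within 2-fold, and all 13 G2/M genes were within 2-fold, with a median of 0.12 that became -0.01 when each cell was given the same weight. The glucose transporter SLC2A3 was the 1 of 7 hypoxia and glycolysis genes that was higher, DNMT3A the 1 of 2 DNA methylation genes that was lower, and 3 p53 targets and the germ-cell-list gene PDPN were within 2-fold. No cell carried a tag, so a treated cell that kept SOX2 counted as H9. SOX2 itself was at 1.80 CPM in the transwell amniotic cells.

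**Figure D3:**
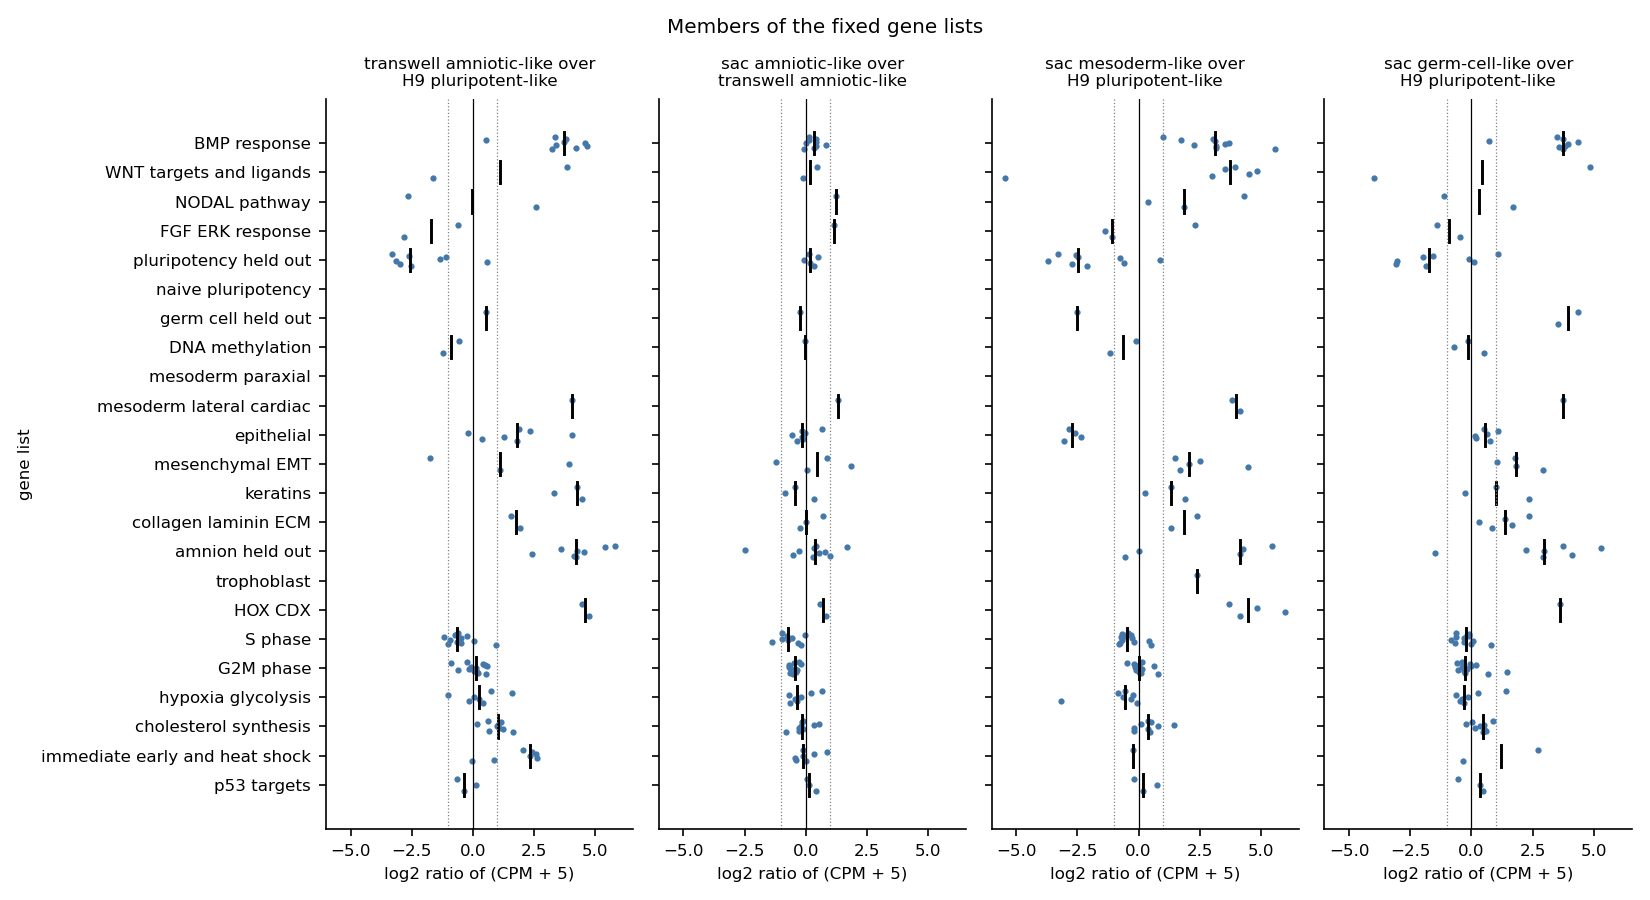
Log2 ratio of (CPM + 5) of each compared list gene (points) and the median of its list (black bars), by list, for 4 comparisons of classes, with dotted lines at 2-fold. All 8 amnion genes and 8 of 9 BMP-response genes lie higher in transwell amniotic cells than in H9.

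Sac and transwell amniotic cells were compared to ask how far amnion made inside a sac differs from amnion made on a membrane. Most list genes were within 2-fold, and the largest ratios, which leave out naming markers, included KRT16, IGF2, TAGLN and ACTA1. Some naming markers differed as well. LUM was at 432 CPM in sac cluster 1, against 38.3, 104 and 34.2 CPM in mixed-library clusters 1, 2 and 3. DLX5 was at 224 against 85.4, 69.8 and 68.7 CPM, and KRT7 at 146 against 267, 582 and 364 CPM. TFAP2A was closer, at 250 against 198, 159 and 182 CPM. KRT16, a keratin of stratified and stressed epithelia, was 6.23-fold (6.01 to 6.47) higher in the sac at 300.2 against 48.2 CPM. PLA2G2A, a secreted phospholipase, was 4.29-fold (4.23 to 4.34) higher at 1659.8 against 387 CPM, and FLRT3, an adhesion protein of embryonic membranes, 4.53-fold (4.32 to 4.74) higher. IGF1 and IGF2, growth factors of the insulin family, were 6.35-fold (5.82 to 6.93) and 5.24-fold (4.85 to 5.67) higher, at 55.1 against 8.68 CPM and 60.3 against 11.5 CPM. Of 1720 IGF1 UMIs in sac amniotic cells 826 were from the 77 cells of cluster 8, and cluster 1 was at 20.8 CPM. METTL7A, a lipid-droplet methyltransferase, was 5.81-fold higher, RAB17, a GTPase of polarised epithelia, 6.68-fold higher, and MEIS2, a partner of HOX proteins, 5.47-fold higher; MMD and the microtubule protein MAP1B were at 167 against 36.4 CPM and 368 against 98.4 CPM. Higher on the transwell were TAGLN, which binds actin in contractile cells, at 7.21-fold (6.96 to 7.48) and 103 against 741 CPM, the secreted matrix protein SPP1 at 8.24-fold (7.52 to 9.06), and the claudin CLDN10 at 3.71-fold (3.58 to 3.83). The skeletal actin ACTA1, the actin-binding COTL1, the tubulin TUBB6 and the natriuretic peptide NPPB were 4.01-fold, 3.16-fold, 2.87-fold and 3.002-fold higher there, as were PSAT1, an enzyme of serine synthesis, and the enzymes MGST1 and ACOT7, at 4.07-fold, 2.39-fold and 2.57-fold.

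Of 97 list genes, 5 were at least 2-fold higher in the sac and 3 at least 2-fold higher on the transwell once 5 CPM was added to both sides; TBX3, PCNA and GINS2 passed 2-fold only without it. The sac-high genes were FST at 305 against 127 CPM, the ERK phosphatase DUSP6 at 135 against 57.7 CPM, ISL1 at 287 against 110.2 CPM, the mesenchymal cadherin CDH11 at 55.3 against 11.9 CPM and CDX2, a regulator of posterior and extraembryonic fates, at 68.5 against 18.1 CPM. The transwell-high genes were fibronectin, FN1, at 172 against 402 CPM, ANXA1, a calcium-dependent membrane protein of the amnion list, at 15.03 against 106 CPM, and the nucleotide-supply enzyme RRM2 at 30.5 against 88.0 CPM. All 9 BMP-response genes were within 2-fold with a median of 0.33 (percentile 99.8), MSX2 at 1051 against 778 CPM and ID1 at 3127 against 2855 CPM among them. All 7 epithelial genes and all 3 keratins of the list were within 2-fold too, with KRT18 at 3994 against 7109 CPM and EPCAM at 1708 against 1915 CPM. All 5 measured pluripotency genes were within 2-fold, including L1TD1 at 437 against 305 CPM. The amnion list had a median of 0.37, percentile 99.9, with TBX3 at 259 against 128 CPM and HAND1 at 2165 against 1613 CPM.

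Proliferation and glycolysis lists leaned lower in the sac cells, though RRM2 was their only member at least 2-fold apart with 5 CPM added to both sides. The S-phase list had a median of -0.74 (percentile 0) and the G2/M list -0.46 (percentile 0), with PCNA at 49.3 against 103 CPM, GINS2 at 28.0 against 59.6 CPM, CDK1 at 104 against 168 CPM and UBE2C at 259 against 421 CPM; the glycolysis list, with LDHA at 251 against 401 CPM and ALDOA at 727 against 1153 CPM, had a median of -0.37 (percentile 0.22). Cholesterol-synthesis genes (9), immediate-early and stress genes (7), p53 targets (3) and matrix genes (3) were within 2-fold without exception, as were WNT5B, SFRP1, HOXB2, HOXB6, PDPN and DNMT1. Sac cluster 1 held 1038 of the 1283 sac cells in this class, and clusters 1, 2 and 3 held the transwell class, and no sac cluster of the class was led by cell-cycle genes. With sac cluster 1 alone, 9 of the 10 sac-high genes stayed at least 2-fold higher, while IGF1 was not once 5 CPM was added to both sides, and all 10 transwell-high genes stayed at least 2-fold lower. Condition, library and flow cell cannot be told apart here.

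**Figure D4:**
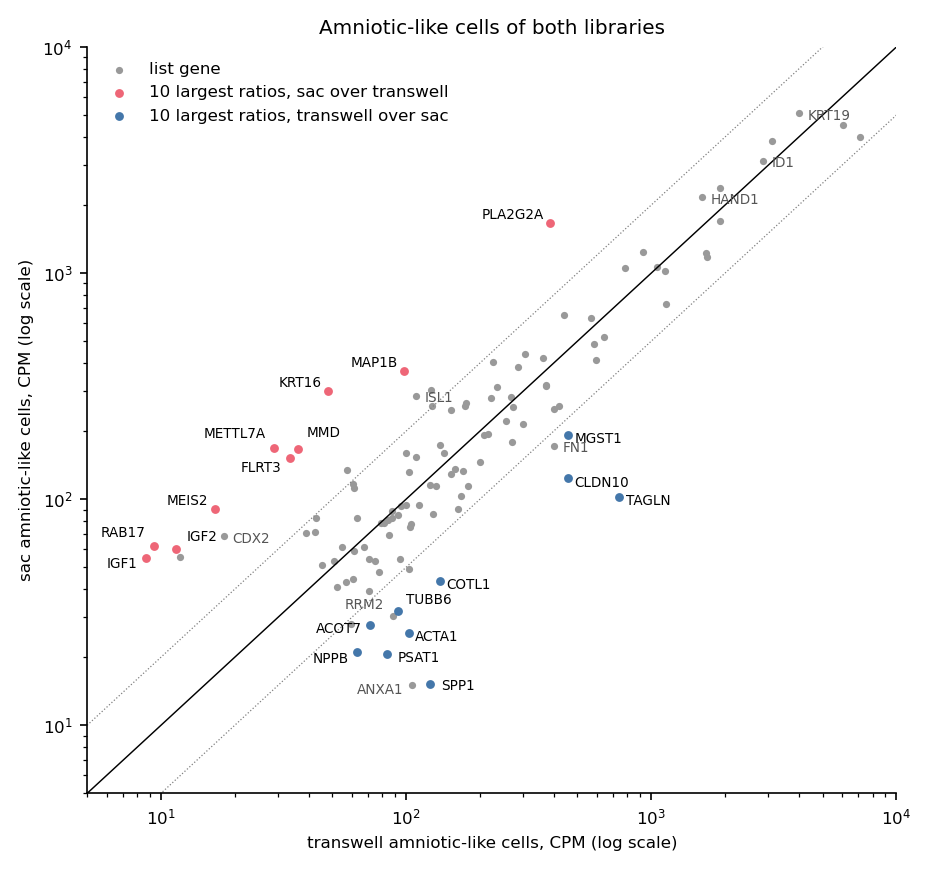
Level in sac amniotic-like cells (vertical, CPM, log scale) against transwell amniotic-like cells (horizontal, CPM, log scale); points are list genes and the genes with the 10 largest ratios in each direction, and dotted lines mark 2-fold. KRT16 at 300.2 against 48.2 CPM and TAGLN at 103 against 741 CPM lie outside the dotted lines, while most list genes lie between them.

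Mesoderm-like sac cells were set against H9 to ask what distinguishes them from the stem-cell state. WNT-target, BMP-response and HOX transcripts were high in them, and epithelial adhesion transcripts low. HAS2, the hyaluronan synthase of migrating mesoderm, was 109-fold (91.8 to 132) higher at 224 against 2.05 CPM, and HAPLN1 62.7-fold (56.4 to 70.0) higher. PRTG, an adhesion receptor of the early mesoderm, was 70.2-fold (61.4 to 80.7) higher, and the neuropeptide gene NTS 34.7-fold (33.5 to 36.0) higher at 1701 against 49.0 CPM. The HOX gene HOXB5 reached 154 against 0.507 CPM and its neighbouring transcript HOXB-AS1 62.7 against 0.344 CPM. RGS13, a regulator of G-protein signalling, was 2888-fold (988 to 14007) higher and the protease inhibitor SLPI 7116-fold (1277 to 281110) higher. RGS13 and SLPI had very few UMIs in all H9 cells, so the size of these folds is uncertain, as the intervals show. LIX1, a regulator of mesenchymal progenitors, was at 80.8 against 0.164 CPM and FAM89A at 233 against 2.52 CPM. Lower were LINC00678, 358-fold (268 to 489), the metallothioneins MT1G and MT1E, 121-fold and 62.4-fold, and TCF7L1, the repressor of WNT targets in stem cells, 16.9-fold (15.1 to 18.8). LECT1, VSNL1, the growth-factor carrier FGFBP3, the kinase AK4, CDCA7L and DPYSL3 were the others, at 19.4-fold, 25.8-fold, 31.9-fold, 16.6-fold, 15.9-fold and 14.5-fold lower.

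Of 105 list genes 37 were at least 2-fold higher in mesoderm-like cells and 16 at least 2-fold higher in H9. WNT targets and ligands were higher in 5 of 6 cases (median 3.75, percentile 100), with NKD1 at 197 against 2.00 CPM, LEF1 at 76.7 against 0.278 CPM, SP5 at 53.9 against 0.0491 CPM and the ligand WNT5A at 123 against 0.654 CPM; the antagonist SFRP1 was 94.1-fold lower. BMP-response genes were higher in 9 of 10 cases, and the ligand BMP4 itself stood at 447 against 4.40 CPM. All 4 HOX and CDX genes were higher, with HOXB6 at 544 against 3.63 CPM and CDX1 at 67.7 against 0.540 CPM. The lateral mesoderm regulators GATA6 and FOXF1 were 1744-fold (597 to 8460.2) and at least 1318-fold higher, with very few H9 UMIs for GATA6 and none for FOXF1. All 5 mesenchymal genes were higher, including CDH11 at 138 against 1.42 CPM and VIM at 929 against 157 CPM, and all 4 epithelial genes lower, including CLDN7 at 14.6 against 159 CPM and EPCAM at 48.6 against 376 CPM. Pluripotency genes were lower in 6 of 9 cases, with NANOG at 1.07 against 54.8 CPM and TERF1 at 95.5 against 1316 CPM, while LIN28A, LIN28B and ZFP42 were within 2-fold. HAND1, CDX2 and TBX3 of the amnion list were higher, at 1275 against 24.2 CPM, 99.1 against 0.327 CPM and 128 against 2.57 CPM, while CTSV and S100A10 were within 2-fold.

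PGF, the growth factor, was the measured trophoblast-list gene and was 9.07-fold higher; KRT19 and KRT8 were 3.76-fold and 2.54-fold higher, and the matrix genes COL6A1 and SPARC 6.18-fold and 2.55-fold higher. FGF19 was at 82.0 against 12.5 CPM while DUSP6 and ETV4 were lower, at 32.0 against 89.9 CPM and 41.6 against 92.8 CPM. PDPN of the germ-cell list was 7.50-fold lower, and ADM, a hypoxia target, 24.0-fold lower. All S-phase (12) and G2/M (13) genes and p53 targets (3) were within 2-fold, and INSIG1 was the 1 of 9 cholesterol genes that was higher. These cells came from the sac library and H9 from the mixed one, so cell type and library cannot be told apart; the median of all compared genes lay at -0.10 on the log2 scale.

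Germ-cell-like sac cells were set against H9 to ask what separates them from stem cells. Most pluripotency genes of the list were lower than in H9, most BMP-response genes higher, and CXCR4 and PDPN of the germ-cell list higher. IGF1 was at 301 against 0.0491 CPM, with 3 UMIs in all H9 cells, 6131-fold (2097 to 29734) higher. GMPR, an enzyme of purine salvage, was 148-fold (118 to 189) higher at 179 against 1.21 CPM, HPGD, which breaks down prostaglandins, 38.8-fold (34.2 to 44.1) higher, and the carbonic anhydrase CA2 24.3-fold (22.6 to 26.1) higher. WNT2, a WNT ligand of placenta and mesoderm with no UMI in H9, was at least 2714-fold higher at 133 CPM, the collagen COL9A2 at 96.9 against 1.80 CPM and the surface protease TMPRSS11E at 81.9 against 0.949 CPM. HAPLN1, PRTG and NTS, also high in mesoderm-like cells, were 65.4-fold, 73.7-fold and 31.5-fold higher. ZIC2 was 314-fold (144 to 857) lower, TCF7L1 34.1-fold (27.0 to 43.7) lower and LINC00678 194-fold (139 to 280.3) lower, and MT1G, the receptor GPR176, C1orf21, CDCA7L, AK4, FGFBP3 and THY1 were the others, between 7.19-fold and 44.9-fold lower.

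Of 100 list genes 33 were at least 2-fold higher in germ-cell-like cells and 9 at least 2-fold higher in H9. Both measured genes of the germ-cell list that had no part in naming were higher, the migration receptor CXCR4 at 129-fold (98.7 to 171) and 118 against 0.916 CPM and PDPN, a surface glycoprotein of primordial germ cells, at 1227 against 102 CPM. NANOG was 2.23-fold (2.12 to 2.34) higher at 122 against 54.8 CPM, alone among 8 pluripotency genes, of which 5 were lower, with PHC1 at 13.9 against 156 CPM, TERF1 at 153 against 1316 CPM and L1TD1 at 159 against 652 CPM, and LIN28A and ZFP42 within 2-fold. BMP-response genes were higher in 7 of 8 cases (median 3.75, percentile 100), with ID4 at 366 against 13.0 CPM and ID1 at 3140 against 275 CPM. Amnion-list genes were higher in 6 of 7 cases, led by CDX2 at 202 against 0.327 CPM and TBX3 at 125 against 2.57 CPM, and S100A10 was lower at 107 against 309 CPM. All 4 mesenchymal genes were higher, with the protease MMP2 at 191 against 20.7 CPM, while 5 of 6 epithelial genes were within 2-fold and EPCAM was higher at 799.7 against 376 CPM. All 3 DNA methylation genes were within 2-fold, with TET1, which starts demethylation, at 53.2 against 35.8 CPM and DNMT3A at 29.0 against 51.5 CPM. EGR1 was at 70.4 against 6.38 CPM, PLK1 at 263 against 93.5 CPM as the 1 of 13 G2/M genes that was higher, and the glucose transporter SLC2A1 at 165 against 58.1 CPM.

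KRT19 and KRT8, COL6A1, LAMC1 and COL6A2, WNT5B, FST, HOXB6 and ISL1 were also at least 2-fold higher, and SFRP1, FOXH1 and DUSP6 at least 2-fold lower, with SFRP1 at 20.5 against 395 CPM. All S-phase (12), cholesterol (9) and p53 (3) genes were within 2-fold. Later germ-cell genes stayed below the minimum level, and DDX4 had 0 UMIs and DAZL 1 in all germ-cell-like cells. As for mesoderm, cell type and library cannot be told apart in this comparison.

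Within the sac library, where the library is shared, germ-cell-like and amniotic-like cells were compared to ask what separates cell types that both had high BMP-response transcripts. The keratins of the list and ACTC1 were higher in amniotic cells, and the S-phase list and CXCR4 in germ-cell-like cells. GMPR was 40.5-fold (34.2 to 48.3) higher in germ-cell-like cells, WNT2 24.6-fold (21.1 to 28.9) higher, and ASRGL1, an asparaginase, 10.6-fold (9.84 to 11.5) higher at 258 against 24.4 CPM. RASD1, a Ras-like GTPase, the glycolytic enzyme ENO2, the MYC target CDCA7, the vesicle GTPase RAB15, the transcription factor DMRTA2, PLBD1 and FAM122C were the others, between 8.29-fold and 34.8-fold higher. On the amniotic side ACTC1 was 16.9-fold (16.4 to 17.4) higher at 2893 against 171 CPM, the matrix protein TINAGL1 21.0-fold (18.6 to 23.7) higher, FLRT3 30.3-fold (25.4 to 36.4) higher, and the muscle ligase TRIM55 91.5-fold (59.7 to 148) higher. The phosphatase UBASH3B, C1orf21, WLS, PPARG, MEIS2 and IGFBP7 were 48.7-fold, 28.0-fold, 11.4-fold, 21.5-fold, 22.3-fold and 14.3-fold higher there. Of 102 list genes 16 were at least 2-fold higher in germ-cell-like and 27 at least 2-fold higher in amniotic-like cells. CXCR4, PDPN and NANOG were higher in germ-cell-like cells, at 118 against 2.76 CPM, 1227 against 129 CPM and 122 against 1.09 CPM, as were LIN28A, ETV4, CDH2, VIM, MMP2, LDHA and TET1.

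All 3 keratins were lower in germ-cell-like cells, KRT19 at 925 against 5089 CPM, and 7 of 9 amnion genes were lower, with IGFBP3 at 25.2 against 2386 CPM and EPAS1 at 17.9 against 651 CPM, while CDX2 was higher at 202 against 68.5 CPM. CLDN4, CDH1 and EPCAM were lower, the adhesion cadherin CDH1 at 55.6 against 249 CPM. BMP-response genes were alike in 8 of 9 cases, with ID1 at 3140 against 3127 CPM, and MSX2 was lower at 368 against 1051 CPM. HOXB2 and HOXB6 were lower at 17.2 against 267 CPM and 102 against 406 CPM. The S-phase list had a median of 0.90 (percentile 99.99), with RRM2 at 112 against 30.5 CPM and UNG at 109 against 40.7 CPM, and PLK1 was higher at 263 against 78.0 CPM. Of 6 immediate-early genes 4 were lower, led by ATF3 at 8.97 against 61.7 CPM and JUN at 25.5 against 117 CPM. FOXH1 was higher while FST, SFRP1, DUSP6, ISL1, L1TD1, CDH11 and SLC2A3 were lower, and the matrix (5), cholesterol (9) and p53 (3) genes were within 2-fold.

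Germ-cell-like and mesoderm-like cells of the sac were compared to ask how the germ line differs from the mesoderm beside it. Germ-cell-like cells had more epithelial and ID1 transcripts, and mesoderm-like cells more WNT-target, HOX and BMP-ligand transcripts. IGF1 was 158-fold (132 to 190.3) higher in germ-cell-like cells, WNT2 77.5-fold (64.0 to 94.7) higher, and PLA2G16, a lipid-modifying enzyme, 25.8-fold (24.2 to 27.4) higher at 459 against 17.8 CPM. DDIT4, a brake on mTOR, and PRODH, which breaks down proline, were 30.6-fold and 31.3-fold higher, the thyroid-hormone binder CRYM 59.9-fold and the amino-acid transporter SLC16A10 50.7-fold; HPGD, RAB15 and ENO2 were at 165 against 7.70 CPM, 187 against 9.75 CPM and 136 against 6.70 CPM. Mesoderm-like cells had more RGS13, 46.8-fold (37.4 to 59.3), SLPI, 62.9-fold (47.3 to 85.7), and HOXB5, 17.96-fold (15.7 to 20.6). The heparan-sulfate enzyme HS3ST1, the lymphatic factor CCBE1, the polarity gene CRB2, FAM89A, LIX1, HOXB-AS1 and HAS2 were 33.7-fold, 26.6-fold, 17.2-fold, 24.8-fold, 17.2-fold, 16.1-fold and 7.23-fold higher there. Of 107 list genes 21 were at least 2-fold higher in germ-cell-like and 20 at least 2-fold higher in mesoderm-like cells.

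All 6 epithelial genes were higher in germ-cell-like cells, with EPCAM at 799.7 against 48.6 CPM and ESRP1, an epithelial splicing factor, at 113 against 7.67 CPM. PDPN was 89.97-fold (84.1 to 96.4) higher, CXCR4 78.6-fold (64.1 to 97.4) higher and NANOG 114-fold (89.6 to 147) higher, the last as the 1 of 7 pluripotency genes past 2-fold. WNT targets and ligands were lower in 4 of 5 cases, LEF1 at 4.49 against 76.7 CPM and NKD1 at 21.6 against 197 CPM, and WNT5B was higher at 222 against 58.0 CPM. The ligands BMP4 and BMP2 were lower, at 44.0 against 447 CPM and 4.17 against 55.0 CPM, as was ID3, while ID1, ID4 and MSX2 were higher, ID1 at 3140 against 553 CPM. HOXB2, HOXB6 and HOXB8, GATA6 and FOXF1 were lower, FOXF1 at 1.93 against 64.7 CPM, and FOXH1, FGF19, CDH11, VIM and PGF were lower as well. ANXA3 and CTSV of the amnion list were higher and HAND1 and S100A10 lower. MMP2, ISL1, EGR1, PLK1, SLC2A1 and SLC2A3 were higher, EGR1 at 70.4 against 3.55 CPM. All 3 keratins and all S-phase (9), cholesterol (9), matrix (5) and p53 (3) genes were within 2-fold.

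Mesoderm-like and amniotic-like cells of the sac were compared to ask how mesenchymal and epithelial cells divide the sac. VIM, N-cadherin and the WNT outputs were on the mesoderm side and E-cadherin, claudins and keratins on the amniotic side. SLPI was 42.7-fold (34.5 to 53.6) higher in mesoderm-like cells, RGS13 20.3-fold (17.7 to 23.3) higher and HAS2 11.2-fold (10.3 to 12.1) higher. CENPV, at 557 against 53.4 CPM, the cyclin CCND1 at 157 against 17.3 CPM, the neuropeptide gene GAL, 7.71-fold, and the actin-sequestering TMSB15A at 218 against 28.3 CPM were higher, as were CD1D, HS3ST1 and CRB2. Amniotic-like cells had more TINAGL1, 87.2-fold (74.8 to 102), IGFBP7, 68.9-fold (58.6 to 81.6), and HPGD, 34.7-fold (31.7 to 38.1). The protease CTSL reached 584 against 29.8 CPM, and SMTNL2, FLRT3, PPARG, TRIM55, ACPP and the muscle LIM protein CSRP1 were 47.8-fold, 31.7-fold, 72.9-fold, 123-fold, 37.9-fold and 17.6-fold higher in amniotic-like cells. Of 110 list genes 22 were at least 2-fold higher in mesoderm-like and 36 at least 2-fold higher in amniotic-like cells.

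All 7 epithelial genes were lower in mesoderm-like cells (median -3.47, percentile 0), with EPCAM at 48.6 against 1708 CPM and CDH1 at 15.8 against 249 CPM, and all 3 keratins were lower, KRT8 at 799.8 against 4496 CPM. VIM at 929 against 82.7 CPM, CDH2 at 50.4 against 4.39 CPM and CDH11 at 138 against 55.3 CPM were higher. SP5, WNT5A, NKD1 and LEF1 were higher among 6 WNT genes, SP5 at 53.9 against 2.79 CPM, and SFRP1 and WNT5B lower. BMP2 and BMP4 were higher at 55.0 against 3.62 CPM and 447 against 81.3 CPM, ID3 was higher at 1303 against 634 CPM, and MSX2, ID1 and ID2 were among 5 BMP-response genes that were lower, MSX2 at 144 against 1051 CPM. GATA6 and FOXF1 were higher at 85.6 against 5.16 CPM and 64.7 against 2.47 CPM and ISL1 lower at 37.4 against 287 CPM; HOXB8, FGF19, FOXH1 and PGF were higher. Of 9 amnion genes 6 were lower, EPAS1 at 8.39 against 651 CPM and CTSV at 111 against 3851 CPM, while HAND1, CDX2 and TBX3 were within 2-fold, HAND1 at 1275 against 2165 CPM. S-phase and G2/M genes had medians of 0.80 and 0.64 (percentiles 99.95 and 99.99), RRM2 at 124 against 30.5 CPM and MKI67 at 56.4 against 28.2 CPM, and 5 of 6 immediate-early genes were lower, with FOS at 3.23 against 85.0 CPM. L1TD1, ZFP42, PDPN, DUSP6 and FST were lower, LDHA was higher and SLC2A1 and SLC2A3 lower, and matrix (3), cholesterol (9) and p53 (3) genes were within 2-fold.

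**Figure D5:**
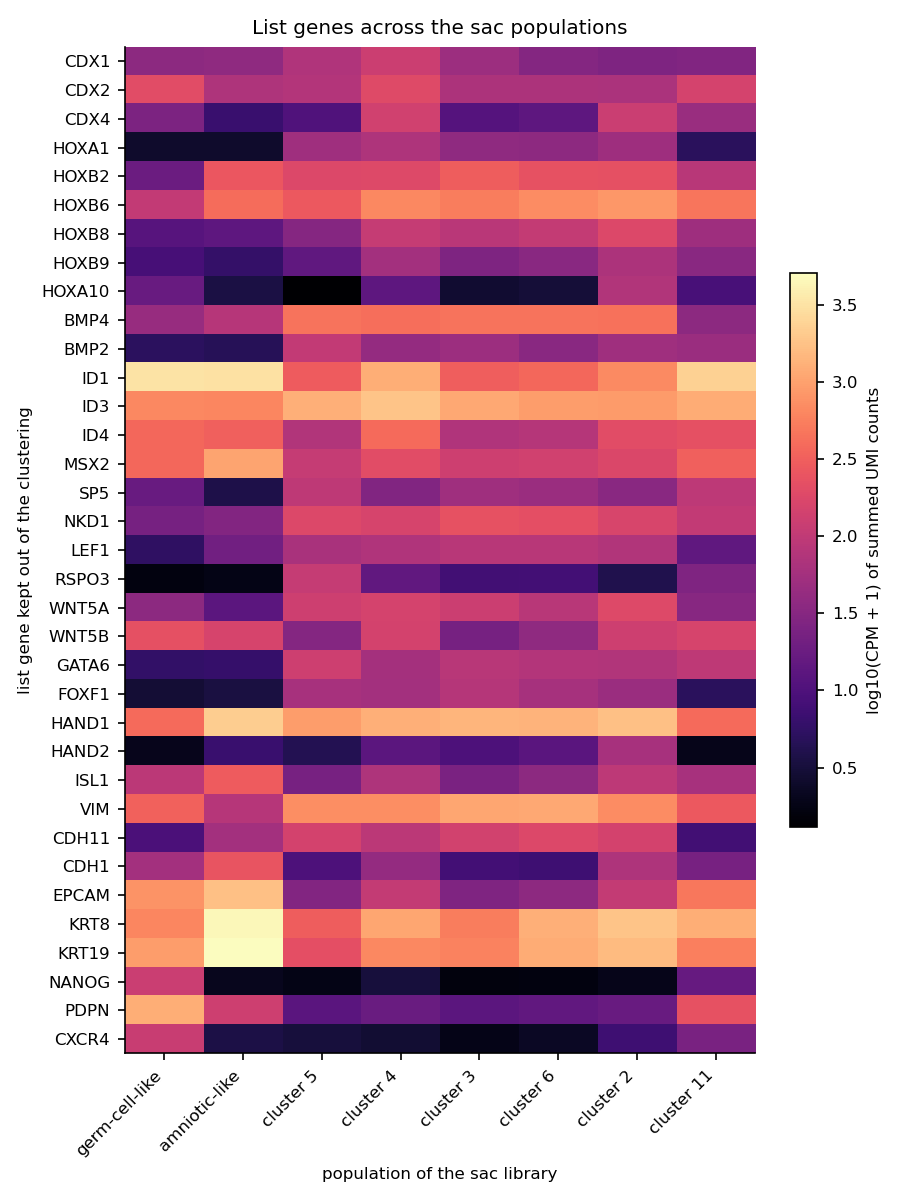
Level of list genes (log10 of CPM + 1, colour) in germ-cell-like and amniotic-like sac cells, the mesoderm-like clusters 3 to 6 and the unnamed clusters 2 and 11. EPCAM is at 1708 CPM in amniotic-like cells and at 26.4 CPM in cluster 3.

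The mesoderm-like class held 4 clusters. Cluster 5 (576 cells) carried T, MIXL1 and EOMES, markers of the primitive streak, among its naming markers. RSPO3, which amplifies WNT signals, was 11.9-fold (10.7 to 13.2) higher than in the other mesoderm-like cells at 109 against 9.16 CPM, and SP5, BMP2 and the pluripotency-list gene L1TD1 were 2.20-fold, 2.47-fold and 2.07-fold higher, while all 3 keratins were lower, KRT19 at 215 against 779 CPM, and ACTC1 9.26-fold (8.75 to 9.80) lower. Cluster 4 (671 cells) had the HOX and CDX list at a median of 0.69 (percentile 100) and the BMP-response list at 0.39 (percentile 100), with 3 of 7 and 2 of 10 genes at least 2-fold higher. The caudal regulators CDX4 and CDX1 were at 135 against 10.9 CPM and 124 against 48.9 CPM, ID1 at 1254 against 319 CPM, ID4 at 389.9 against 73.9 CPM and WNT5B at 147 against 28.3 CPM. EPCAM and CLDN6 were higher there, at 106 against 29.5 CPM and 164 against 61.3 CPM. Cluster 6 (468 cells) had more ACTC1, 6.03-fold (5.92 to 6.15) at 1970.2 against 327 CPM, more of the chaperone HSPA5 at 528 against 149 CPM, more PCNA at 216 against 89.6 CPM, CDK1 at 369 against 123 CPM and PGK1 at 413 against 176 CPM, and its cells were the deepest of the class, with a median of 29137 UMIs. Cluster 3 (860 cells) had 0 list genes at least 2-fold higher and 6 at least 2-fold lower, with CDX4 at 10.5 against 56.5 CPM, ID4 at 70.5 against 191 CPM and WNT5B at 21.8 against 74.6 CPM, and RGS13, SLPI and IGF2 were 2.21-fold, 1.68-fold and 2.34-fold higher. The unnamed cluster 2, against all mesoderm-like cells, had more of the limb and posterior regulators PITX1, 10.6-fold (9.90 to 11.4), HOXA10, 17.2-fold (15.1 to 19.6), and HAND2, 6.74-fold (6.12 to 7.44). Its keratins were all higher, KRT19 at 1542 against 659 CPM, as were the basement-membrane collagen COL4A1 at 77.2 against 19.0 CPM, HGF at 93.8 against 12.2 CPM, HEY1 at 122 against 28.9 CPM and ACTC1 at 3695 against 692 CPM.

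The amniotic-like class of the sac held minor clusters beside cluster 1. Cluster 8 (77 cells) had more of several transcripts that were also high in germ-cell-like cells, with POU5F1 at 1616 CPM. Naming markers of germ-cell-like cells stayed lower. SOX17, NANOS3 and PRDM1 were at 47.5, 26.2 and 6.87 CPM, against 523, 262 and 89.7 CPM in germ-cell-like cells. TFAP2C was at 259 against 490 CPM. Against cluster 1, IGF1 was 24.8-fold (22.2 to 27.6) higher at 516 against 20.8 CPM, CRYM 16.4-fold (14.9 to 18.1) higher, PDPN 7.46-fold (6.95 to 8.01) higher, MMP2 at 226 against 45.5 CPM and SLC2A1 at 496 against 143 CPM, while IGFBP3, EPAS1 and ACTC1 were 8.12-fold, 5.20-fold and 9.01-fold lower. Cluster 7 (101 cells), led by FOXI1, a regulator of ion-transporting epithelial cells, had more DLL1, a Notch ligand, 7.83-fold (6.40 to 9.58) at 62.6 against 7.98 CPM, more BNIP3 at 86.1 against 21.8 CPM, more CLDN10 at 350.4 against 105 CPM and less SFRP1, MSX1 and WNT5B. Cluster 9 (67 cells) had a median of 6836 UMIs per cell and held 2.24-fold (2.21 to 2.28) more of the nuclear transcript MALAT1 than cluster 1. Without it, all 20 genes with the largest ratios between sac and transwell amniotic cells kept their side and at least 2-fold.

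Genes of some fates stayed below the minimum level. No member of the naive pluripotency list or of the paraxial mesoderm list reached the minimum level in any of the 7 comparisons of classes; KLF17, a naive-state regulator, had 0 UMIs in germ-cell-like and 0 in H9 cells, which at a limit of 3 counts allows up to 0.118 and 0.0491 CPM, and MSGN1, a regulator of paraxial mesoderm, was at 0.0789 CPM in mesoderm-like cells. The lists held no naming markers, and the mesoderm markers MESP2 and TBX6 were at 67.0 and 42.0 CPM in sac cluster 5. The low list genes therefore do not show that paraxial mesoderm is absent. PGF apart, no trophoblast-list gene reached the minimum level, with CGA at 0.953 and VGLL1 at 21.3 CPM in transwell amniotic cells. Neural regulators such as PAX6 at 0 CPM and SOX1 at 0.0962 CPM in sac amniotic-like cells, and the endothelial cadherin CDH5 at 0.0158 CPM in mesoderm-like cells, were at or near 0. Markers of 1 class were also found in others. In sac amniotic-like cells 14 germ-cell and mesoderm markers had a median of 4.15% of their level in their own class, from 1.56% for SOX17, at 8.14 CPM, to 30.1% for APLNR. SOX17 was uneven there, at 47.5 CPM in cluster 8, and GABRP in H9 was at 6.46 against 226 CPM in transwell amniotic cells.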

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

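The tests for droplets holding free RNA and for doublets, and the MALAT1 value of sac cluster 9, were chosen only after the results they address had been seen.

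Genes higher in sac than in transwell amniotic cells, 65 in all with KRT16, PLA2G2A, IGF2 and FLRT3 among them, could reflect RNA leaking from other sac cells or the scaling of the totals. The largest share of a germ-cell or mesoderm marker seen in sac amniotic cells was 30.1%, for APLNR. A leak of that size covered the excess of 6 of the 65 genes, or 9.23%, which argues against a leak for the set as a whole. IGF1 and CDX2, both higher in germ-cell-like than in sac amniotic cells, had an excess within that size. At the median marker share of 4.15% a leak covered 0% of the 65 genes, IGF1 and CDX2 included. APLNR was also at 48.5, 51.0 and 31.7 CPM in transwell amniotic clusters 1, 2 and 3, so its share is not leaked RNA alone. A leak stays open for IGF1 and CDX2 only at the largest share. Under median-of-ratios scaling 98.5% stayed at least 2-fold higher, but its factor between these classes was 1.01 and moved almost no gene, so this tests nothing and scaling stays open. The sac environment, the biological explanation in the design, and differences between libraries, flow cells and device stay open, since each condition has a single library.

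Clusters 10 of the sac and 7 of the mixed library stood out because their cells, which enter no comparison, had few UMIs and almost no mitochondrial transcripts, with a median of 0.0523% and 0.0821%. They might be nuclei or cells that lost cytoplasm, but the nuclear transcript MALAT1 was not higher in them, at 0.162 times the level of the closest cluster in the sac and 0.644 times in the mixed library. Droplets with only free RNA would carry amniotic markers in cluster 7 at the mean of the mixed library, and these lay at 0.0455 of it. Cluster 7 instead held the pluripotency transcripts NANOG, DPPA4, POU5F1 and SOX2, and cluster 10 MESP1 and SNAI2. What these cells are stays open, no biological explanation was tested, and sac cluster 9, with few UMIs and MALAT1 at 2.24 times its level in cluster 1, was not part of these tests.

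Sac cluster 11 was 45 cells that took no name and enter no comparison of classes. It stood out by the endoderm regulator FOXA2 at 43.8 CPM beside SOX17, a naming marker of germ-cell-like cells. Of their other markers, NANOS3 was at 20.5 against 262 CPM in germ-cell-like cells and TFAP2C at 35.1 against 490 CPM. ALPL was at 72.1 against 69.3 CPM. Doublets of average cells of the named classes could hold no more of these genes than the classes themselves. FOXA2 and APOA1 together were 20.6 times as high as in germ-cell-like cells, the highest named class. This argues against doublets of average cells only. FOXA2 had flagged the cluster beforehand, so the outcome was known, and doublets with a rare FOXA2-high cell are not excluded. Several other endoderm markers were low in cluster 11, with APOA2 at 19.5 CPM, HNF4A at 1.95 CPM and FOXA1 at 0.974 CPM. HHEX, TTR and SHH had no UMI. An endoderm-like cell type is a hypothesis that stays open, since it rests on few cells and few markers and was found and tested in the same library.

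Mixed-library cluster 5, which was named neither amniotic-like nor mesenchymal, stood out by the claudin CLDN10 at 2264 CPM, against 458 CPM in transwell and 124 CPM in sac amniotic cells. No explanation was tested for it.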

How the results depend on the processing

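Naming every cluster and leaving out low-UMI clusters were chosen only after the results had been seen. 232 other shares and counts stayed within their interval or 1.5 times the main count. No single-gene ratio of at least 2-fold in the main setting changed direction. Smaller ratios, shares and counts were not scored for a change of direction. Of 99 list medians 2 changed sign with equal weight for cells and 2 after thinning, none of them above 0.124 at first.

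Shares moved where clusters split or merged and lost or took a name. At resolution 0.3 amniotic-like cells were 20.1%, mesoderm-like 32.1% and germ-cell-like 20.5% of the sac, and amniotic-like 19.8% of the mixed library. At resolution 1.0 they were 20.2%, 40.8%, 20.3% and 43.0%. With both libraries clustered together they were 18.9%, 58.6%, 21.3% and 51.7%, with pluripotent-like 39.2% of the mixed library. Variable genes from all genes gave 44.5% mesoderm-like and 49.7% mixed amniotic-like cells. Naming every cluster gave 57.8% mesoderm-like and 39.2% pluripotent-like cells, and without low-UMI clusters sac amniotic-like cells were 20.3% of all kept cells and 20.7% of those left.

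With a minimum of 500 genes mixed amniotic-like cells were 48.8%, and with 3000 genes 38.8%, beside 38.5% pluripotent-like and 56.6% mesoderm-like. With at most 5% mitochondrial UMIs amniotic-like cells were 23.4% of the sac and 57.3% of the mixed library, mesoderm-like 32.1% and pluripotent-like 29.7%. With doublets kept mesoderm-like cells were 47.7% and mixed amniotic-like cells 34.9%.

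Counts of list genes past 2-fold grew without a minimum level, because more genes were counted. Transwell amniotic against H9 cells then gave 71 higher and 29 lower, mesoderm-like against H9 67 and 28, germ-cell-like against H9 64 and 16, germ-cell-like against mesoderm-like 37 and 36. 30 were higher in germ-cell-like and 44 in mesoderm-like than in sac amniotic cells, and 13 in sac than in transwell amniotic cells. At resolution 0.3 the last was 9, and H9 exceeded transwell cells in 28; their cause was not tested. With a pseudocount of 1 CPM 5 exceeded sac cells in the transwell. Of ratios of single genes, 2916 moved beyond their narrow counting intervals and 5829 did not. The 20 genes with the largest ratios kept their side and at least 2-fold in every comparison and setting run, except that between sac and transwell amniotic cells 19 did at a pseudocount of 20 CPM and 16 at resolution 0.3. A minimum does not enter a ratio, so ratios have no value without it. Thinning every cell to 10000 UMIs left out 157 transwell and 99 sac amniotic cells and moved no count of list genes past 1.5 times; depth limits genes under the minimum level.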

Other observations

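The comparisons of mixed-library cluster 5 and of sac cluster 11 were chosen only after their values had been seen.

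Mixed-library cluster 5 (359 cells) carried TFAP2A, GATA3 and WNT6 beside the mesenchyme markers COL1A1, COL1A2 and POSTN. The other mesenchyme markers, LUM, COL3A1, COL6A3 and DCN, were at 2.05, 0.237, 0.237 and 0 CPM. Against transwell amniotic cells NPPB was 6.02-fold (5.79 to 6.26) higher, CLDN10 4.95-fold (4.87 to 5.02) higher, and PSAT1 and ASNS, enzymes of serine and asparagine synthesis, 4.73-fold (4.56 to 4.90) and 3.10-fold (2.995 to 3.20) higher. The contractile genes ACTA1 and CNN1 were 3.80-fold and 2.85-fold higher, BMP4 was at 216 against 84.3 CPM and VIM at 138 against 43.0 CPM. PPARG, EPAS1, IGFBP3 and CTSV, high in amniotic cells, were 5.33-fold, 6.87-fold, 6.74-fold and 3.52-fold lower, and all 3 keratins and 7 epithelial genes of the lists were within 2-fold.

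Of the 10 genes with the largest ratios in transwell over sac amniotic cells, 7 were also at least 2-fold higher in cluster 5 than in transwell amniotic cells. Among all compared genes 9 of 25 transwell-high genes were, against 2 of 65 sac-high genes and 28 of 2951 in all.

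Against germ-cell-like cells, sac cluster 11 had more of the gap-junction gene GJA1, 3.99-fold (3.67 to 4.34), of RGS5, 4.02-fold (3.62 to 4.44), and of the lipoprotein gene APOC1, 2.52-fold (2.17 to 2.93). FOXH1 and NKD1 were higher, at 146 against 51.2 CPM and 101 against 21.6 CPM, as was FN1 at 419.7 against 89.9 CPM. NANOG, PDPN and CXCR4 were lower, at 15.6 against 122 CPM, 235 against 1227 CPM and 23.4 against 118 CPM, and IGF1 23.8-fold (13.9 to 44.7) lower. SOX17 stood at 345 CPM and NANOS3 at 20.5 CPM in cluster 11.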
